A study of Homo sapiens with 12 samples.

How the data were processed

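RNA sequencing was used to compare captured and parental cells of MDA-MB-231, an established human triple-negative breast cancer cell line, meaning a line classed as lacking the estrogen, progesterone and HER2 receptors. Per the labels, total RNA from cultured cells was extracted with a spin-column micro kit and libraries were made with a standard Illumina workflow. The submitters' processing notes name Trimmomatic version 0.32, STAR version 2.3.0e and featureCounts version 1.4.4, and the genome builds hg19 and GRCh37. Whether counting used the strand, and how reads with several matches were treated, is not given in the sources used here. Reads from overlapping or antisense genes, and from near-identical gene copies, therefore cannot be assigned with certainty.

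The deposited table holds raw counts of reads per gene, made by the authors and not normalized, for 60234 genes in 12 libraries. All 12 columns were matched to their sample by the labels. The labels give 2 populations (fast and parental), 2 batches and 3 libraries of each population in each batch, and the series describes the libraries as technical replicates. Nothing says that the libraries came from separate captures or cultures, so the p-values measure only the spread between libraries, which may be technical. Total counts ran from 53267145 to 75944907 per library. Levels are in CPM, the counts of a gene scaled to a common library total, so that a gene at 1 CPM had about 53.3 counts in the shallowest library. Intervals on counts cover counting error only, since PCR copies were not marked by molecular identifiers.

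From the counts, edgeR 4.0.16 (R 4.3.3) was run with TMM normalization, its default low-count filter (a minimum count of 10 and a minimum total of 15, by population and batch) and a robust quasi-likelihood fit. The filter left 22668 genes. The main model had batch as an additive term and population as the effect over all 12 libraries. A model with 1 mean per population and batch gave the effect within each batch and the difference of the effect between batches. Adjusted p-values are Benjamini-Hochberg values, with 0.05 as the threshold. Normalised levels are TMM-normalised CPM, and log2 fold changes are fast over parental with their standard errors (SE). Where a population had a total of 0 counts, a fold is given as a lower bound against a floor of 3 counts over the population's libraries. With 1 or more counts, the ratio of normalised totals is given with its exact 95% Poisson interval.

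Before the data were examined, 32 gene lists were fixed, along with the rule for named genes and the alternative settings. The lists covered migration, adhesion, matrix, metastasis, signalling, metabolism, cell cycle, immune and stress genes, RNA-quality signs and markers of other cell types. Of their entries, 980 were matched to the count table by gene ID, 12 by the table's symbol and 17 by an older name, and 2 were unmatched (CD24 and PECAM1). Lists were tested with camera on log2 CPM (prior count 2, limma 3.58.1) with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The named genes were the 12 with the largest rise and the 12 with the largest fall among genes with a symbol other than a clone name, a mean of at least 5 CPM and a call of the same sign in both batches. To these were added up to 4 called members of each list by size of change, the 4 genes on each side with the largest difference of effect between batches at a mean of at least 5 CPM, and VIM, CDH1, ESR1, PGR and ERBB2 as markers of the line. Some genes that the rule names are not reported here. The genes CDKN2A, CDKN2B and MTAP, and the genes that end the runs along chromosomes were chosen after their values were seen.

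The steps were tested on simulated counts drawn from the libraries' means and dispersions, in a run of 22121 genes. Changed genes were taken from those with a mean of at least 1 CPM, libraries were drawn independently, and no general batch effect was added. Far fewer genes were changed than were called in the real data. The rates below therefore hold for these settings and need not carry over to weaker genes or to the real libraries. For fast against parental, 84% of 50 genes changed by 1.25-fold, 88% of 50 changed by 1.5-fold and 100% of 50 changed by 2-fold were recovered. For the difference between batches, 80% of 50 genes changed by 1.5-fold and 92% of 50 changed by 2-fold were recovered. Of 21781 unchanged genes that passed the filter, 18 were called for fast against parental, and of 22021 with no difference of effect between batches, 5 were called for that difference.

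The reference annotation at hand, GENCODE release 29 on GRCh38, is of another build than the counts. It was used by gene ID for chromosome and gene order, and no coordinates are given. The transcript sequences of the same release gave the GC content and length of each gene's longest transcript. It matched 95.1% of the 22668 genes, and 15925 genes with at least 1 CPM in a population entered the analysis of gene order. Each gene was compared with the median log2 fold change of its 20 nearest genes on each side. Runs were found by splitting each chromosome recursively where the mean of fold changes (limited to a log2 value of 1 either way) changed by more than in any of 100 permuted gene orders, with at least 20 genes per run.

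Alternatives were DESeq2 1.42.0 and limma-voom in place of edgeR, other normalizations, no filter and a stricter filter, a replicate block, no batch term, sums of the libraries of each population and batch, an average of the within-batch effects and each library left out in turn. An offset for the fold change of neighbouring genes was added after seeing the data. Tables were handled in Python 3.11.15 with pandas 2.3.3, and tests of counts and shares used SciPy 1.17.1.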

Results

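The series compared MDA-MB-231 cells that had been captured by the path they migrated along, called fast, with the parental cells they came from. RNA was sequenced in 12 libraries, 3 of each population in each of 2 batches, at 53267145 to 75944907 counts per library. Mitochondrially encoded genes took 2.08% to 3.41% of the counts of a library. In all 12 libraries CDKN2A, CDKN2B and MTAP, neighbours on chromosome 9, had 0 counts. The line's mesenchymal marker VIM, an intermediate filament protein, stood at 6912 CPM in fast and 5050 CPM in parental cells (log2 fold change 0.45 ± 0.02 SE). The epithelial cadherin CDH1 had at most 4 counts in any library and was not tested. ESR1, the estrogen receptor, stood at 0.139 CPM in each population, and ERBB2, the HER2 receptor, at 59.0 CPM in fast and 62.4 CPM in parental cells (edgeR adjusted p = 0.982 and 0.015). The small difference of ERBB2 was no longer called without a batch term (edgeR adjusted p = 0.113) or without fast batch 1 replicate 1 or 2, parental batch 1 replicate 3 or parental batch 2 replicate 2 (0.0514 to 0.0821). The progesterone receptor PGR was higher in fast cells, at 2.05 against 0.477 CPM (log2 fold change 2.12 ± 0.16 SE). The first principal component held 60.2% of the variance and separated the populations, and the second held 13% and separated the batches. All 12 pairs of libraries of the same population and batch differed by more than counting noise (index of dispersion 3.36 to 8.48). Each library was treated as a separate unit, which this spread does not justify by itself, since the libraries are described as technical replicates.

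**Figure D1:**
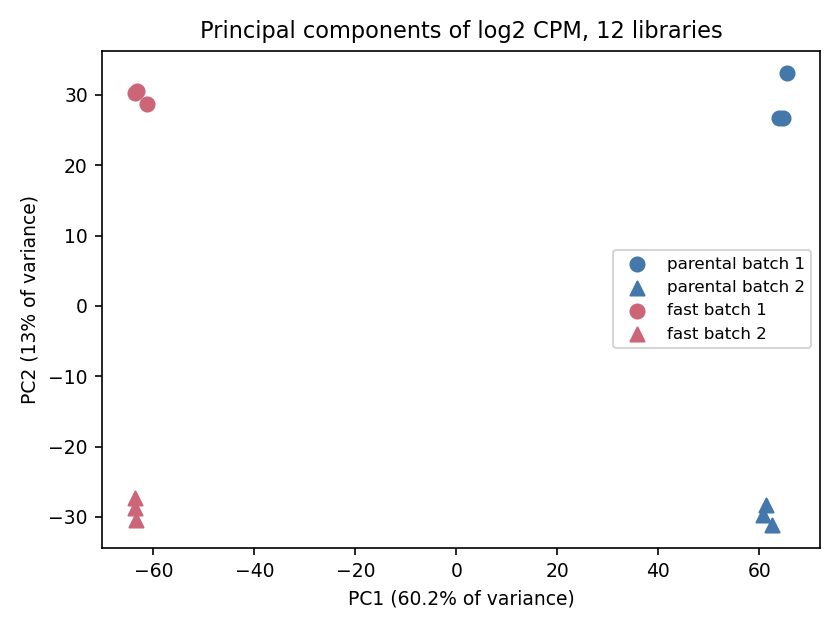
Principal components of log2 CPM of the 12 libraries: the x axis is the first component (60.2% of variance), the y axis the second (13%), and each point is 1 library, coloured by population and shaped by batch. Fast libraries lie between -63.63 and -61.2 on the first component and parental libraries between 60.66 and 65.51.

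The main question was which genes differ between fast and parental cells. The largest rises at a mean of at least 5 CPM were in CD22 (ENSG00000012124), a sialic acid-binding lectin known from B cells, from 2.31 to 38.5 CPM (log2 fold change 4.06 ± 0.06 SE, n = 6 libraries each), and CLDN4, a tight junction claudin, from 1.82 to 27.4 CPM (3.91 ± 0.07 SE). SLC14A1, a urea transporter, rose 11.5-fold, and B3GNT7, a glycosyltransferase of keratan sulfate synthesis, rose 8.49-fold. The elongation factor EEF1A2 rose 7.5-fold, the TNF receptor TNFRSF1B 6.25-fold, the calcium-binding protein CALB2 5.39-fold and the phosphodiesterase PDE2A 5.2-fold. The neurotrophin receptor NGFR rose from 22.7 to 116 CPM, the zinc finger gene ZNF114 from 4.16 to 20.6 CPM, and the EGF receptor ligand EREG from 3.73 to 20.03 CPM. The call for EREG was lost on sums of the 3 libraries of each population and batch, which leave 4 samples (edgeR adjusted p = 0.198). SPANXA2, an X-linked cancer-testis gene with near-identical copies, so that its own share of the reads is uncertain, rose 6.47-fold.

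The largest falls were losses of nearly all reads. CXCR4 (ENSG00000121966), the chemokine receptor for CXCL12, had 10 counts over the 6 fast libraries against 11605 over the 6 parental libraries, a ratio of 1180 (95% Poisson interval 643 to 2470). The adhesion protein TENM1 had 2 counts against 44800, a ratio of 22800 (6320 to 188000). No count in fast cells was found for DMD, which encodes dystrophin, with 8970 in parental cells and a level at least 3050-fold lower, for TSPYL5, at least 2340-fold lower, or for the cancer-testis genes MAGEA6 and MAGEA11, at least 4060-fold and 1320-fold lower. MAGEA6 has near-identical relatives, so its counts are uncertain. The kinase NRK, the membrane protein LRRN1 and the angiomotin AMOT had 4 counts each against 16626, 7154 and 5049. The splicing regulator MBNL3 and the kinase MST4 had 29 and 32 counts against 13634 and 11461. Of the 12 genes with the largest falls, 9 lie on the X chromosome.

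In edgeR's quasi-likelihood test, 7234 genes were higher and 7140 lower in fast cells, 63.4% of the 22668 tested, at an adjusted p under 0.05. By at least 2-fold, 903 were higher and 1568 lower. With a filter at a mean of 1 CPM these last counts were 449 and 635. The median absolute log2 fold change was 0.32 between populations and 0.14 between batches. The p-values speak for these libraries, which are described as technical replicates.

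**Figure D2:**
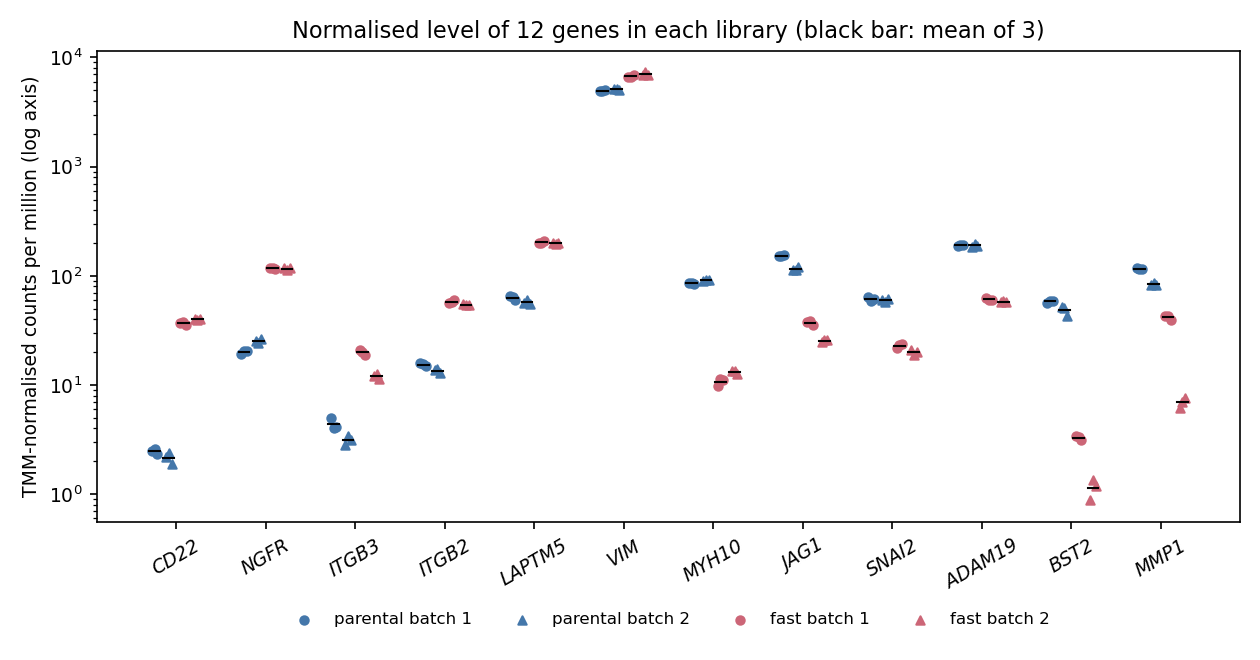
TMM-normalised CPM of 12 genes (x axis) in each of the 12 libraries on a log axis, coloured by population and shaped by batch, with a black bar for the mean of 3 libraries. CD22, NGFR, ITGB3, ITGB2, LAPTM5 and VIM are higher in all 6 fast libraries, and the other 6 genes are lower in all 6.

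Genes of the migration machinery went both ways. Of 68 tested genes of the actin cytoskeleton list, 36 were higher, 26 lower and 6 not past the threshold. The 4 members that moved most fell. MYH10, the heavy chain of nonmuscle myosin IIB, fell from 88.0 to 11.9 CPM (log2 fold change -2.89 ± 0.04 SE), the Ena/VASP protein EVL from 18.5 to 2.47 CPM, the actin nucleation regulator WASF3 from 15.6 to 2.81 CPM and the smooth muscle protein TAGLN from 27.1 to 8.28 CPM. The list did not pass the camera test (adjusted p = 0.731).

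Integrins and focal adhesion genes were more often higher, 23 of 36 against 10 lower, with no list call (camera adjusted p = 0.0989). Integrin beta 3, ITGB3, rose from 3.77 to 16.01 CPM and the leukocyte integrin chain ITGB2 from 14.4 to 56.3 CPM. ITGB4, the laminin-binding beta chain of hemidesmosomes, rose 3.34-fold, and the collagen receptor chain ITGA2 rose from 102 to 225 CPM (log2 fold change 1.12 ± 0.03 SE). Of 39 extracellular matrix genes, 15 were higher and 18 lower. The proteoglycan SPOCK1 fell from 29.9 to 1.35 CPM, the matricellular protein SPARC from 3.02 to 0.48 CPM, and the X-linked collagen IV chains COL4A5 and COL4A6 from 6.88 to 0.626 CPM and from 0.545 to 0.0124 CPM. Of 36 matrix proteases and inhibitors, 22 were higher and 9 lower. The collagenase MMP1 fell from 100.2 to 24.3 CPM, with log2 fold changes of -1.48 in batch 1 and -3.60 in batch 2 and no call on the sums (adjusted p = 0.322), and ADAM19 fell 3.22-fold, from 190.1 to 59.2 CPM. The membrane-type protease MMP16 rose from 2.83 to 12.9 CPM.

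Mesenchymal and epithelial markers did not move as blocks. Of 17 mesenchymal markers, 8 were higher and 6 lower. SNAI2, the transcription factor Slug, fell from 60.7 to 21.4 CPM (log2 fold change -1.51 ± 0.04 SE) and the cadherin CDH11 from 805 counts to 4, while PRRX1 rose 2.75-fold at under 2.1 CPM. Of 27 epithelial junction and keratin genes, 14 were higher and 5 lower. CLDN4 led the rises, and LSR, a tricellular junction protein, fell from 10.7 to 3.09 CPM. Of 12 basal breast markers, 5 were higher and 5 lower, and of 13 luminal line markers, 5 were higher and 5 lower. None of these 4 lists passed (camera adjusted p of 0.841, 0.199, 0.841 and 0.841).

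Genes tied in earlier work to metastasis of this line were compared next. Of 13 genes linked to lung metastasis, 3 were higher and 7 lower, and of 9 linked to bone metastasis, 4 were higher and 4 lower, with no list call (adjusted p = 0.429 and 0.866). In the bone list CXCR4 and MMP1 fell and the cytokine IL11 rose from 39.3 to 96.9 CPM. In the lung list SPARC and MMP1 fell and EREG rose.

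Signalling lists also split. TGF-beta response genes had 10 higher and 7 lower of 24, with TGFBI, a secreted matrix protein, up from 59.5 to 155 CPM, SNAI1 up from 1.17 to 2.83 CPM and PMEPA1 down from 33.6 to 7.37 CPM (adjusted p = 0.198 on the sums). YAP/TAZ targets had 13 higher and 9 lower of 24, with ANKRD1 up from 209.8 to 462 CPM, and IGFBP3 and tissue factor F3 down from 266 to 78.1 CPM and from 411 to 138 CPM. Of 35 receptor tyrosine kinase and ligand genes, 16 were higher and 13 lower. The ligand PDGFB rose from 0.416 to 4.68 CPM and IGF2 from 0.931 to 3.52 CPM, and TGFA fell from 23.1 to 5.49 CPM. Of 28 stem-like state, Notch and Wnt genes, 9 were higher and 15 lower. The Notch ligand JAG1 fell from 134 to 31.3 CPM (log2 fold change -2.11 ± 0.03 SE) and WNT5A from 11.8 to 3.25 CPM, while JAG2, another Notch ligand, rose from 1.33 to 3.18 CPM. None of the 4 lists passed (camera adjusted p of 0.575, 0.841, 0.736 and 0.429).

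Of 21 glycolytic enzymes and transporters, 15 rose and 3 fell, and this list was the 1 of 32 past the threshold (camera adjusted p = 0.0277), with an adjusted p = 0.59 with an estimated correlation. The changes were small. The enolase ENO2 rose from 37.1 to 64.0 CPM, the lactate exporter SLC16A3 from 255 to 405 CPM (log2 fold change 0.67 ± 0.03 SE), the glucose transporter SLC2A3 from 16.4 to 27.7 CPM and the aldolase ALDOC from 2.41 to 4.27 CPM. The gene list glycolysis had an adjusted p of 0.0707 with a filter at a mean of 1 CPM, 0.0692 on sums of the libraries, and 0.125 with fold changes centred on those of neighbouring genes, a setting chosen after seeing the data. Of 27 hypoxia response genes, 9 were higher and 13 lower (camera adjusted p = 0.422). The secreted glycoprotein STC1 fell from 109 to 20.7 CPM, adrenomedullin ADM from 209 to 63.6 CPM (adjusted p = 0.173 on the sums) and the carbonic anhydrase CA9 from 0.71 to 0.0138 CPM. Of 72 nuclear-encoded respiratory chain genes, 31 were higher and 27 lower, and of 13 mitochondrially encoded genes, 2 were higher, MT-CO3 by 0.38 ± 0.09 SE in log2, and 0 lower in edgeR's test. Cholesterol synthesis genes had 9 higher and 14 lower of 24, with the X-linked sterol enzyme NSDHL down from 37.6 to 20.98 CPM. These 3 lists had camera adjusted p-values of 0.841, 0.429 and 0.277.

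Of 40 S-phase genes, 25 were higher and 10 lower, and of 46 G2/M genes, 18 were higher and 15 lower (camera adjusted p = 0.0989 and 0.841). Thymidylate synthase, TYMS, rose from 379 to 721 CPM and ORC6, of the origin recognition complex, from 40.4 to 65.7 CPM, while the mitotic genes CDC20, KIF20A and KIF4A fell from 436 to 269, 304 to 186 and 134 to 80.8 CPM. Of 78 cytosolic ribosomal protein genes, 22 were higher and 41 lower (camera adjusted p = 0.0989). RPL10 fell from 902 to 502 CPM, RPSA from 995 to 586 CPM and RPL39 from 316 to 189.9 CPM, while RPL13 rose from 656 to 1068 CPM. Ribosomal protein genes have many pseudogene copies that can share reads. Across the 78 genes, which are not independent replicates, the log2 fold change had a Pearson correlation of 0.89 and a Spearman correlation of 0.84 with the median of their neighbours on the chromosome (permutation p = 1e-05 for each, the smallest that 100000 resamples give).

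Immune and stress genes were mixed. Of 45 interferon-stimulated genes, 18 were higher and 16 lower. BST2, the restriction factor tetherin, fell from 53.4 to 2.21 CPM (adjusted p = 0.104 on the sums) and OAS1 from 0.926 to 0.223 CPM, while IFIT1 and IFIT2 rose from 10.6 to 34.1 CPM and from 17.0 to 59.3 CPM. MHC class I presentation genes had 6 higher and 10 lower of 18, with HLA-F down from 2.99 to 0.923 CPM and the regulator NLRC5 up from 14.3 to 21.8 CPM. NF-kB targets and cytokines had 12 higher and 5 lower of 29. CXCL1 fell from 7.28 to 2.16 CPM and TNFAIP2 rose from 36.9 to 83.3 CPM. Unfolded protein and ATF4 stress genes had 16 higher and 9 lower of 31. PHGDH, of serine synthesis, rose from 18.5 to 47.0 CPM and the amino acid transporter SLC7A5 from 836 to 1561 CPM, while SESN2 fell from 28.4 to 13.7 CPM. Immediate early and heat shock genes had 14 higher and 8 lower of 30, with KLF4 up from 30.3 to 55.9 CPM (adjusted p = 0.189 on the sums), the co-chaperone BAG3 up from 115 to 198 CPM and NR4A1 down from 1.90 to 1.15 CPM (edgeR adjusted p = 0.0444). NR4A1 had a log2 fold change of 0.04 in batch 1 (adjusted p = 0.886), which was not called, and of -2.07 in batch 2. The call for NR4A1 was lost with a replicate block (adjusted p = 0.146), without a batch term, with limma-voom, on the sums and without fast batch 1 replicate 3 or any 1 library of batch 2 (0.0511 to 0.0944). The 5 lists had camera adjusted p-values of 0.841, 0.57, 0.419, 0.547 and 0.547.

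Markers of other cell types and of RNA selection were checked in the same way. Of 20 leukocyte markers, 5 could be tested, with 3 higher and 1 lower. The lysosomal protein LAPTM5 rose from 60.1 to 200.4 CPM and CD68 from 92.2 to 178 CPM. Of 18 fibroblast markers, 5 could be tested, with 3 higher and 1 lower, and of 14 endothelial markers 9, with 5 higher and 2 lower. ESAM, an endothelial adhesion molecule, rose from 95.8 to 197 CPM and EGFL7 from 7.55 to 21.04 CPM. The endothelial receptor TIE1 fell from 7.37 to 2.85 CPM, the macrophage receptor CSF1R from 1.38 to 0.772 CPM and the collagen chain COL1A1, of the fibroblast list, from 14.2 to 9.32 CPM. Replication-dependent histone genes, whose transcripts lack a poly(A) tail, had 1 higher and 11 lower of 22, with HIST1H1C down from 42.0 to 21.3 CPM. Small structural RNAs had 1 higher and 2 lower of 11. The 5 lists had camera adjusted p-values of 0.215, 0.42, 0.277, 0.252 and 0.841. Adjusted over the list alone, the counts of called members were the same as over all genes for 27 of the 32 lists, and 1 member more was called in each of the other 5. Fry, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes, called 23 lists. The median, mean and camera direction of a list differed in sign for the mesenchymal, actin, bone metastasis, YAP/TAZ, interferon, G2/M and basal lists. None of these passed with camera, while fry called the mesenchymal, G2/M and basal lists.

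Position on the chromosomes was examined after seeing the data. Of 526 X-linked genes with at least 1 CPM, 88.2% were lower in fast cells, with a median log2 fold change of -0.61 (quartiles -0.91 and -0.31), against 46.2% of 15399 genes on other chromosomes. At least 16-fold lower in fast cells were 42 of the X-linked genes (8%) and 93 of the others (0.6%; Fisher's exact test, odds ratio 14.3, p = 1.21e-29). The opposite, at least 1 CPM in fast and at least 16-fold lower in parental cells, held for 3 genes. Fisher's test takes genes as independent units, which they are not, since neighbours moved together, so its p-value is too small. The 42 also hold the 9 X-linked genes among the 12 largest falls, so the test is in part a restatement of those falls. Of the runs of neighbouring genes found, 12 had a median log2 fold change of at least 0.4 either way, and all had the same sign in both batches. On chromosome 16 a run of 350 genes ending at FAM157C was higher (median 0.59), and on chromosome 18 a run of 73 genes ending at ZNF519 (0.81). On chromosome 18 a run of 105 genes from PIAS2 to PARD6G was lower (-0.67), as were 436 genes on chromosome 3 from TRNT1 to CHMP2B (-0.46) and 49 genes on chromosome 1 from ZDHHC18 to PTPRU (-1.06). A run of 29 genes on chromosome 5 from PCDHB2 to PCDHGC5 (1.23) holds protocadherins, some of which share exons, so not all of its genes are separate measurements. Several genes named above moved as their neighbours did. TYMS on chromosome 18 had a log2 fold change of 0.93 beside a neighbour median of 0.91, SESN2 on chromosome 1 had -1.06 beside -1.07, KIF4A on the X had -0.73 beside -0.83, and RPL13 on chromosome 16 had 0.71 beside 0.56. Centred on their neighbours, TYMS had 0.015 (edgeR adjusted p = 0.656) and NLRC5 0.023 (0.719), so that their calls were lost. CD22 and CXCR4 did not move as their neighbours did, with neighbour medians of 0.07 and 0.13.

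**Figure D3:**
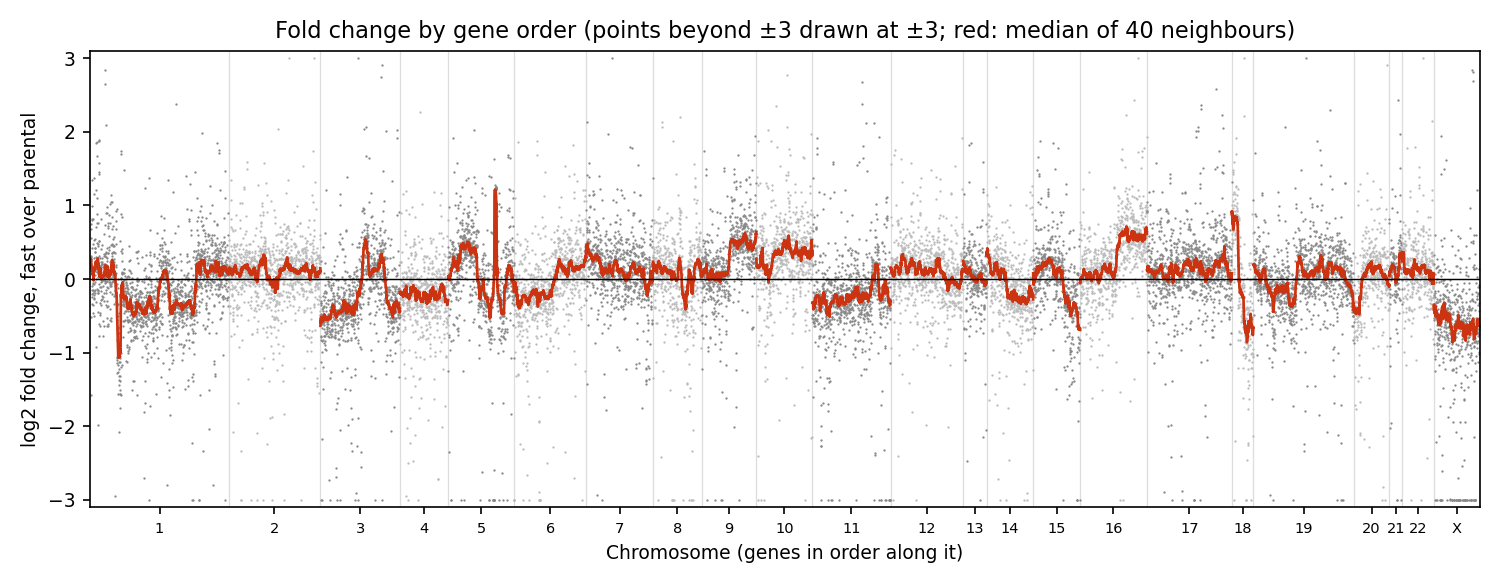
Log2 fold change, fast over parental, of 15925 genes in their order along chromosomes 1 to 22 and X (x axis); grey points are genes, with values beyond 3 drawn at 3, and the red line is the median of the 40 nearest genes. The line lies near -0.61 on the X and near 0.59 on the latter part of chromosome 16.

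The batches were then compared with each other. Fast differed from parental cells in 12718 genes in batch 1 and 12698 in batch 2 (edgeR), with 5223 higher and 5212 lower in both batches and 88 called with opposite signs. Across all tested genes the log2 fold changes of the batches had r = 0.889, and across those of at least 1 CPM r = 0.959. Genes are not independent replicates. The size of the effect differed between batches for 1223 genes, 92 of them by at least 2-fold, and for 734 of the 1223 the effect was called with the same sign in each batch. The MHC class II genes HLA-DRA, HLA-DRB1, HLA-DRB5 and HLA-DPA1 were lower in fast cells by more in batch 1 than in batch 2. HLA-DRA stood at 13.4 ± 1.52 CPM in fast and 78.2 ± 2.05 CPM in parental cells in batch 1 (SD, n = 3 each), and at 20.3 ± 0.27 and 32.8 ± 1.47 CPM in batch 2. HLA-DRB1 and HLA-DRB5 are near-identical, so their shares are uncertain. PTGS2, the inducible cyclooxygenase, was higher in fast cells in batch 1, at 31.1 ± 3.21 against 12.2 ± 0.76 CPM, and lower in batch 2, at 3.27 ± 0.56 against 6.57 ± 0.32 CPM. The cytokine IL24 had log2 fold changes of 0.49 and -1.73, and MMP1 fell by more in batch 2. On sums of the 3 libraries of each population and batch, 14 of the genes that the rule names lost their additive call, among them the 4 MHC class II genes (adjusted p from 0.189 to 0.426), MMP1, WTAPP1, EREG, BST2, PMEPA1, ADM, KLF4, NR4A1 and ERBB2. WTAPP1 overlaps MMP1 on the opposite strand, so its counts cannot be told from those of MMP1 without strand. Between the batches themselves 8202 genes differed, 972 by at least 2-fold, and 4001 differed on the sums.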

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

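The tests of neighbouring genes, of near-absent genes and of the stress and cytokine lists, and all counts over other splits of the libraries, were chosen after the result was seen, and the test that left out each library in turn was written before.

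The effect of population differed between batches for 1223 genes in edgeR's test of the difference itself. Of these 1223, among 22668 tested genes, 827 had a more negative and 396 a more positive log2 fold change in batch 2. Of 110 genes named in the text, 33 were among the 1223, 25 with a more negative and 8 with a more positive value. Some of the 110 were named through this same test and others for large changes, so their share does not stand for all genes. The values that follow are the log2 fold change of fast over parental cells in batch 2 minus that in batch 1, each past the threshold in that test. Among genes with large rises, EEF1A2 had -0.68, CALB2 -0.29, PDE2A -0.38, NGFR -0.34, ZNF114 -0.58 and EREG -1.22. Of other cell type markers, TIE1 had -0.80 and COL1A1 0.36. Of adhesion, protease and TGF-beta genes, ITGB4 had 0.36, MMP1 -2.12, IL11 -0.41, TGFBI 0.37, PMEPA1 0.98 and SNAI1 -1.30. Of YAP/TAZ, hypoxia and glycolysis genes, IGFBP3 had -0.26, F3 -0.37, STC1 -0.30, ADM -0.79 and SLC2A3 -0.27. Of immune, metabolic, stress and Wnt genes, BST2 had -1.27, IFIT2 -0.31, TNFAIP2 -0.25, SESN2 -0.35, KLF4 -0.70, NR4A1 -2.10 and WNT5A -0.90. The MHC class II genes had 1.85 (HLA-DRA), 1.72 (HLA-DRB1), 1.52 (HLA-DRB5) and 1.41 (HLA-DPA1). PTGS2 had -2.36, IL24 -2.21 and WTAPP1 -2.17.

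For the 8 genes that the rule names for the largest differences, no single library carried the difference, since leaving out each library in turn kept at least 91.5% of it, while the count of 1223 genes moved between 878 and 1257. The 58 genes of the early response, heat shock and cytokine lists had a median difference of effect of -0.306 in log2. The central 95% of 10000 lists matched on expression ran from -0.07 to 0.02. All 27 of the 58 genes past the threshold had a lower ratio of fast over parental cells in batch 2. This does not say that their level was lower. The ratio was also lower in batch 2 for 827 of all 1223 called genes. The matched lists were drawn gene by gene, while the members of the 2 lists varied together (estimated correlation 0.361 and 0.41). The range is therefore too narrow for such lists, and the comparison does not decide the cause. A response to handling or culture that differed between the populations and batches is an untested candidate explanation for the 58 genes, and it remains open for the others. The design gives no biological difference between the batches, so no biological explanation was tested. The splits leave undecided whether chance is excluded for this count (1223, 980 with a replicate block): 2 of 30 reached it, the real one and one with 1723 genes, which exchanged the batch labels of all 6 parental and 2 fast libraries and so turned the batch difference into a difference of effects, and simulated counts with no such difference gave 5 calls among 22021 genes.

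Genes that lie next to each other on a chromosome changed together between the populations. For the correlations over all 15925 genes, log2 fold changes were limited to a value of 1 either way. These limited values had r = 0.548 with the median of the 40 neighbours, against at most 0.018 in 100 permuted gene orders. This argues against a chance order. The value was 0.549 after adjustment for GC content, transcript length and level, which argues against these as the cause. Within batch 1 it was 0.534 and within batch 2 it was 0.543. Each batch held both populations, so a difference between the batches could not give this pattern. For batch 2 against batch 1 the value was 0.095, small but above the highest of its permuted orders (0.024). Ribosomal protein genes, which share a function and lie on many chromosomes, followed their neighbours with r = 0.89, computed without that limit. A DNA copy number that differs between the populations would give this, as would any other regional cause. Such a copy number difference is a hypothesis that stays open, since no DNA was analysed here.

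Genes expressed in parental cells and at least 16-fold lower in fast cells numbered 135, of which 42 lie on the X. A single deleted stretch of the X is argued against by their nearest expressed X genes, of which 28.6% were near absent too (exact 95% interval 19.2% to 39.5%). The interval takes the 84 neighbour positions as independent, although adjacent near-absent genes count each other, so it is too narrow. Another cell line in the fast libraries is argued against by the opposite class, which held 3 genes where unrelated lines would differ both ways. This covers only fast libraries made wholly of an unrelated line, and a mixture of cells in either population was not tested. Of the 484 other X genes, 87.2% were lower in fast cells, a share that follows from that over all X genes seen before, so that it is no separate test, and loss of an expressed X copy in fast cells stays open as a hypothesis. The 93 near-absent genes on other chromosomes remain open. They are not all separate measurements, since several are alpha protocadherins on chromosome 5, which share exons. A further 10 lie in 1 run on chromosome 11, from USP28 to GLB1L2.

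The counts were taken over 30 of the 200 relabellings of libraries within each batch or population, the real one included. Those of genes higher (7234), lower (7140), higher by 2-fold (903), lower by 2-fold (1568), higher in both batches (5223) and lower in both batches (5212) were each reached by 1 split, the real one, with 0 as the highest other. The 8202 genes that differed between batches were also reached by the real split alone (highest other 1). Every other split mixed libraries that the first 2 principal components had already set apart, so few calls could come of it. The splits thus argue only against a chance labelling of these libraries, with 1 of 30 as the smallest share that they could give. The libraries are described as technical replicates, so these splits say nothing about chance differences between captures or cultures. A chance assignment is not excluded for the number of gene lists past the threshold, since 23 of 30 splits had at least as many as the real 1 (highest other 6). Within a batch the 10 splits are too few, with 12718 genes in batch 1 and 12698 in batch 2 and 0 as the highest other in each.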

How the results depend on the processing

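The offset for neighbouring genes was chosen after the data were seen, and all other alternatives before. Under every alternative run, several counts stayed within 1.5 times their value. They were those of genes higher, lower, changed within a batch, called in both batches and differing in effect between batches. Of the calls, 48.2% to 51.6% were higher in fast cells. Each fit scaled the libraries so that fold changes centred near 0 (median log2 fold change -0.035 to 0.015). The near-even split therefore follows largely from the scaling and does not test the balance of changes in the cells. A filter at a mean of 1 CPM, which tests 16189 genes, left 449 genes higher and 635 lower by 2-fold. Sums of the 3 libraries of each population and batch, which leave 4 samples, gave 4001 genes that differ between batches. The number of gene lists past the threshold was 0 with the 1 CPM filter, 0 on sums, 0 with an estimated correlation, 0 with the neighbour offset and 23 with fry. The cause of these moves was not tested. With a replicate block, used although libraries of the same number did not pair (r from -0.422 to 0.223), 7024 genes were higher and 6942 lower, 892 and 1560 by 2-fold, 980 differed in effect and 1 list passed (glycolysis, adjusted p = 0.044). The block used the replicate numbers of the sample titles, and some columns of batch 1 carry other numbers in the deposited counts. The neighbour offset reversed KIF4A (0.10), PSMB10 (-0.077) and SESN2 (0.011), which its construction explains, since it removes the shift of the neighbours, and 6 named genes lost their call, among them TYMS (0.015), NDUFV2 (0.011) and NLRC5 (0.023), which had shifted by about as much as their neighbours. ESR1, which was not called, changed sign with voom (-0.061), upper-quartile scaling (-0.007), the block (-0.036), no batch term (a value that rounds to 0), the neighbour offset (-0.16) and 5 libraries left out in turn (all libraries: -0.263 to 0.288). With the average of the within-batch effects, 2 named genes gained a call. The mesenchymal list turned to down with fry (adjusted p = 0.0486), and lists short of the threshold on both sides were counted as unchanged whatever their direction. Leaving out 1 library gave 6965 to 7302 genes higher, 6851 to 7161 lower, 894 to 969 and 1573 to 1674 by 2-fold, 11947 to 12758 in batch 1, 11974 to 12844 in batch 2, 4950 to 5250 and 4863 to 5058 in both batches, 878 to 1257 that differ in effect, 7496 to 8022 between batches and 1 to 2 lists. The 2 lists came without parental batch 2 replicate 3, where the list ribosomal passed (adjusted p = 0.0322). No stricter filter was run for genes that differ between batches.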

Other observations

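The comparison with neighbouring genes was chosen after the data were seen. Further members of the gene lists moved in the same direction as their neighbours on the chromosome, and those below were picked as examples. Once centred on their neighbours, 137 named genes kept their sign and call, 6 lost their call and 4 changed sign. NDUFV2 on chromosome 18, of the respiratory chain, rose from 93.9 to 168 CPM (log2 fold change 0.84 beside a neighbour median of 0.83, and 0.011 once centred on the neighbours, which ends its call), and PSMB10 on chromosome 16, an immunoproteasome subunit, rose from 23.1 to 31.3 CPM (0.44 beside 0.52). On the X, NDUFA1 fell from 54.9 to 30.6 CPM (-0.84 beside -0.64) and the DNA polymerase subunit POLA1 from 72.5 to 45.2 CPM (-0.68 beside -0.54).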
